A study of Mus musculus with 2 samples.

How the data were processed

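RNA of 2 sorted cell populations of postnatal day 4 mouse hair follicles was measured on 1 Affymetrix expression array each. Follicles had been freed from the dermis enzymatically and dissociated, and dead cells and large differentiated cells had been gated out, per the labels' protocols. Total RNA was labelled as biotinylated cRNA by the standard Affymetrix procedure. The deposited values are linear signal intensity values per probe set, made by the authors with MAS5 in Affymetrix Expression Console, per the submitters' processing notes, which give no version. The 2% trimmed mean of all probe sets was 500.0 on both arrays, so each array had been scaled to one target. MAS5 subtracts mismatch probe signals and gives no negative values, and its low values are noisy. Detection calls and probe-level files were not used here. The genome build is not given in the sources used here and no coordinates are given.

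Gene names came from the platform annotation as supplied, with symbols looked up by Entrez ID in a table of mouse RefSeq genes (GRCm38.p6). No symbol needed updating, and 34754 of 34958 single-gene probe sets had their Entrez ID in that table. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9160 other non-control probe sets had none in the annotation used. The 34958 include 13 control probe sets. Probe sets with several or no symbols and all control probe sets were left out of gene counts, and the rest gave 18193 genes.

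Before the data were examined, the groups, the settings, the alternatives, the rule for named genes and 33 lists were fixed. A gene was represented by the probe set with the highest mean log2 signal. Signals below the 40th percentile of all pooled signals (57.8) were set to it. A gene was measured if at least 1 array reached this floor, which left 13252 genes, 1718 of them with 1 array at the floor. Their ratios are lower bounds and are written as at least N-fold. Ratios are early bulge over non-bulge ORS. The highest signal of the TrpnX negative control probe sets was 28.1, below the floor. With 1 array per group no test between the populations was possible. Genes were counted by size, at 2-fold and 4-fold. For a list of 3 or more measured genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these 2 arrays and is no test of the populations. Medians outside the 2.5th to 97.5th percentile are those called shifted, and several lists share genes: 16 of the 35 adult bulge genes stand in other lists too. The number of arrays limits the precision of every value.

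The named genes were, among genes above the floor on both arrays whose measured probe sets all had 1 direction, the 12 largest ratios each way. They were also the 5 brightest genes each way with the other array at the floor, the gate genes, and up to 4 measured genes of each list with the largest absolute ratio. Genes outside this rule are marked as chosen after their values were seen. Of 466 genes in the lists, 446 matched a probe set with that gene alone, and the other 20 were not analysed here.

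There were 22 gene lists: the gate genes, adult bulge stem cell genes, basal keratinocyte and hemidesmosome genes, upper follicle and junctional zone genes, companion layer keratins, hair matrix regulators, structural genes of the hair shaft and inner root sheath, epidermal differentiation, sebaceous gland, DNA replication and mitotic genes, cell cycle inhibitors, secreted Wnt inhibitors, Wnt targets, Wnt ligands and Frizzled receptors, the BMP and TGF-beta, Hedgehog and Notch pathways, extracellular matrix, actin contractile and microRNA processing genes, and immediate early and heat shock genes that respond to dissociation. A further 11 lists held markers of dermal fibroblasts, dermal papilla, melanocytes, immune cells, endothelium, pericytes and smooth muscle, Schwann cells, Merkel cells, skeletal muscle and erythroid cells, and sex-linked transcripts.

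Alternatives were median centring, quantile normalization and loess scaling (span 0.4) of the arrays, floors at the 20th and 60th percentile, no floor, a pseudocount in place of the floor, the mean over probe sets of a gene, probe sets without an _s, _x or _a suffix only, a count of probe sets, and random lists with no matching. The sebocyte list of the closing observations was also taken without Pcx, an alternative chosen after seeing the data. The median of that list was resampled 10000 times over its genes for its bootstrap SD. The procedure was tested on simulated arrays with the real mean signals, on which 12736 genes were measured. Their noise was the spread between probe sets of one gene (0.338 on the log2 scale). Of 100 genes changed by 1.5 on the log2 scale 94 were found at least 2-fold apart in the right direction, and of 100 changed by 2.5 all 100 were. Of 12536 unchanged genes, 24 (0.19%) were 2-fold apart. Of 200 lists of 20 unchanged genes, 7 (3.5%) had a median outside the central 95% of random lists. The changed genes were drawn only from genes well above the floor, and the same spread was used at all signals. These shares therefore do not cover the noisier low signals. This simulation holds only the spread between probe sets and not that between animals or sorts. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 drew the plots.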

Results

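Gene expression was measured in 2 epithelial cell populations sorted from the back skin of mouse pups at postnatal day 4, an age at which the first coat of hair is growing. The pups were of the CD-1 strain and carried a red reporter under the keratin 14 promoter, which is active in basal keratinocytes, and a green reporter for Sox9, a transcription factor of hair follicle stem cells. The early bulge sample held cells bright for both reporters. The bulge is the part of the follicle in which its stem cells reside. The non-bulge outer root sheath (ORS) sample held cells bright for the red reporter and negative for the green one. The ORS is the outermost epithelial layer of the follicle. Each population was measured on 1 array, so no ratio has a replicate check and no p-value is given. Each array gave a signal for 45101 probe sets, of which 64 were controls. The signals ran up to 28952 on the early bulge array and 25506 on the ORS array, and their medians were 102.2 and 88.0. Of the other 45037 probe sets, 62.0% on the early bulge array and 58.0% on the ORS array lay at or above a signal of 57.8, which served as the floor below which a signal was not ordered.

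Genes of the upper follicle, the sebaceous gland and bulge stem cells were among those higher on the early bulge array. Genes of connective tissue, the hair matrix and the cell cycle were among those higher on the ORS array. Of 13252 measured genes, 968 were at least 2-fold higher on the early bulge array and 634 on the ORS array, and 248 and 175 were at least 4-fold higher. After loess scaling the 2-fold counts were 811 and 743, and the share of them higher on the early bulge array was 52.2% in place of 60.4%. Among genes above the floor on both arrays, the largest ratios towards early bulge were those of Cst6, a cysteine protease inhibitor (46.1-fold, signals 2753 and 59.8), and Krt79, a keratin of the upper follicle (45.2-fold, 18506 and 409.7). Krt6a, a keratin of the companion layer, was 38.4-fold higher. The transcription factor Foxc1 was 38.0-fold higher and Nfatc1, a transcription factor of quiescent bulge cells, 32.2-fold higher. Capns2 (37.1-fold), Aldh3a1 (33.9-fold), Psapl1 (23.6-fold), Klk7 (22.3-fold), Fa2h (21.8-fold), Tcim (19.0-fold) and Npnt (17.2-fold) completed these 12 genes. Klk7 is a skin protease, Fa2h a fatty acid hydroxylase and Npnt the basement membrane protein nephronectin. A further 5 genes were below the floor on the ORS array and were brightest on the early bulge array. They were Sdr16c6 (at least 75.7-fold higher), Acsbg1 (at least 41.9-fold), Nebl (at least 40.0-fold), Bcan (at least 38.4-fold) and Far2 (at least 30.2-fold). Acsbg1 and Far2 are enzymes of fatty acid activation and reduction. Other probe sets of Nebl gave a log2 ratio as low as 0.69, and those of Bcan one of 2.41.

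Towards the ORS array, the largest ratios were those of the actin-binding protein Tagln (34.1-fold), the matrix protein Thbs2 (33.0-fold), the collagen crosslinking enzyme Lox (31.9-fold) and the proteoglycan Lum (29.9-fold). Mycl (25.4-fold), Ccn3 (23.6-fold), Dpt (22.5-fold), Tmtc1 (19.4-fold), Ccdc80 (19.3-fold), Col6a2 (15.6-fold), Ror2 (15.5-fold) and Lhfp (15.4-fold) followed. The 5 brightest genes on the ORS array that were below the floor on the early bulge array were Fgf5 (at least 33.3-fold), C1qtnf3 (at least 25.4-fold), Ogn (at least 20.1-fold), Dpep1 (at least 13.2-fold) and Pdgfra (at least 12.8-fold). Fgf5 is a growth factor of the ORS that ends hair growth, and Pdgfra is a receptor of skin fibroblasts, whose other probe sets gave a log2 ratio as weak as -0.08. Across genes above the floor on both arrays, log2 signals of the 2 arrays correlated with r = 0.927 over 11534 genes, which are not independent replicates. Probe sets of one gene gave a measure of technical spread only. The difference in log2 ratio between them had an SD of 0.48 over 9106 pairs. Of 701 genes at least 2-fold apart that had another measured probe set, 621 (88.6%) had all of them in the same direction, and in 415 (59.2%) at least 1 of them was also 2-fold apart. Among 59 such genes named by the fixed rule, 21 had another probe set less than 2-fold apart or of opposite sign, and its value is given beside the gene. The rest kept direction and 2-fold size on every measured probe set, but not always the size of the ratio. Weaker log2 ratios included 1.085 for Npnt (main 4.104), -1.147 for Ogn (-4.332) and -1.604 for Col6a2 (-3.959). Stronger ones included 4.723 for Tcim (4.249) and -4.931 for Ccn3 (-4.559). The counts depend on the floor. With a floor at the 20th percentile, 1870 genes were at least 2-fold higher on the early bulge array and 984 on the ORS array.

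**Figure D1:**
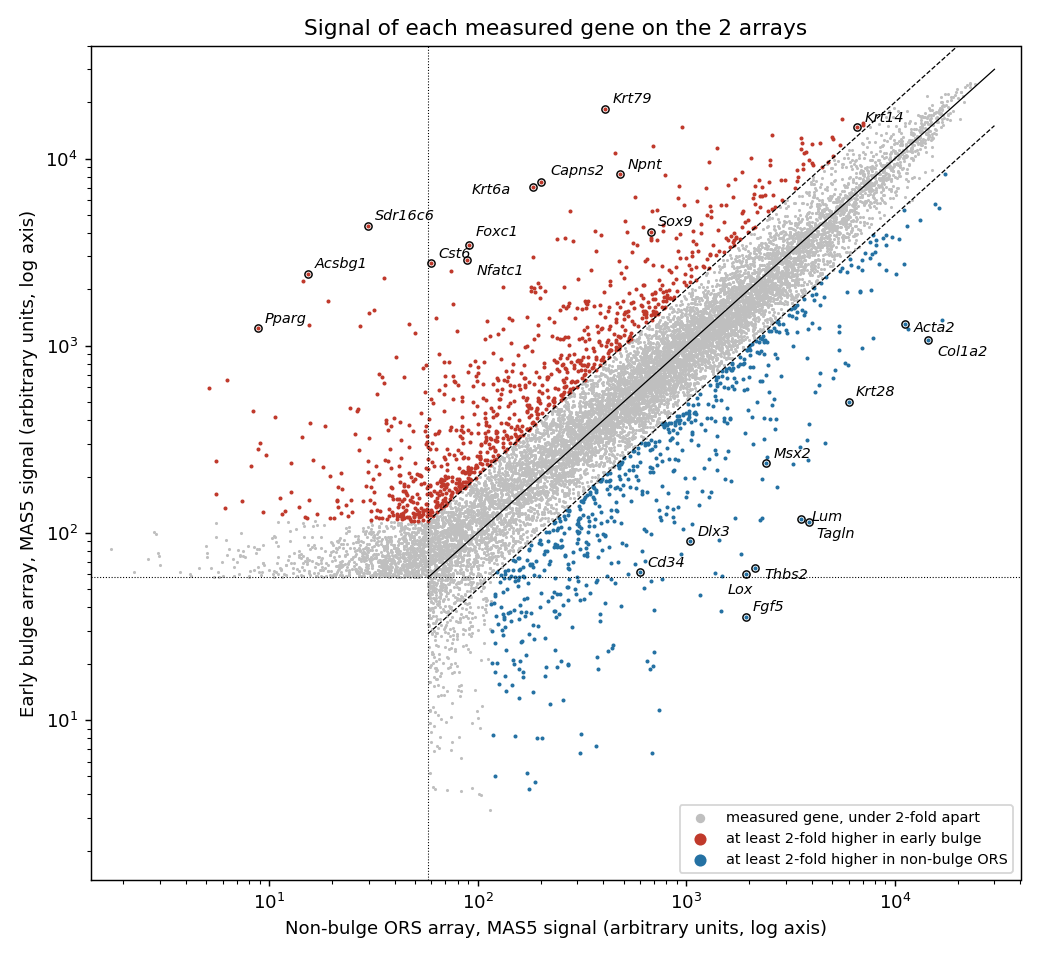
Signal of each measured gene on the early bulge array (vertical log axis) against the non-bulge ORS array (horizontal log axis), in arbitrary MAS5 units, with 1 array per population. The solid line marks equal signals, the dashed lines 2-fold differences and the dotted lines the floor of 57.8. Red and blue points are the 968 and 634 genes at least 2-fold higher on either array, with the floor applied.

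The genes behind the sorting gates and 13 of 34 stem cell genes were at least 2-fold higher on the early bulge array. Sox9 was 6.01-fold higher (signals 4061 and 676) and Krt14 2.23-fold higher (14706 and 6609). Only the green reporter, for Sox9, differed between the gates, so the Sox9 ratio checks the labels only. Both sorts were bright for the keratin 14 reporter, so the gates do not fix the Krt14 difference. Its log2 ratios ran from 1.15 to 2.43 over 3 probe sets, and its cause was not tested. The other probe sets of Sox9 gave a log2 ratio as low as 0.30. Among 34 measured genes of the adult bulge list, 13 were at least 2-fold higher on the early bulge array, 2 were at least 2-fold higher on the ORS array and 19 were less than 2-fold apart. At any size, 25 had the higher signal on the early bulge array and 9 on the ORS array. Their median log2 ratio was 0.81, at the 100th percentile of 10000 random lists of the same size matched on mean signal. Besides Foxc1 and Nfatc1, the activin antagonist Fst was 8.08-fold higher. The 2 genes higher on the ORS array were Bmp6 (2.42-fold), named here after its value was seen, and Cd34. Cd34, the surface protein used to sort adult bulge cells and also present in dermal cells, was 9.75-fold higher (603 against 61.8) on that array, where dermal fibroblast markers were also higher. Lgr5 and Lhx2, a receptor and a transcription factor of follicle stem cells named here after their values were seen, differed little, with log2 ratios of -0.11 and -0.03.

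Genes of the upper follicle and the sebaceous gland, and part of those of the differentiating epidermis, were higher on the early bulge array. All 10 measured genes of the upper follicle and junctional zone list had a higher signal there, 9 of them by at least 2-fold, and their median log2 ratio was 2.14 (100th percentile). After Cst6 and Krt79, the largest ratios were those of the antimicrobial peptide Defb6 (at least 20.3-fold) and the transcription factor Gata6 (at least 9.60-fold). Of 12 sebaceous gland genes, 7 were at least 2-fold higher and none was lower, with a median of 1.33 (100th percentile). The lipid droplet gene Cidea was at least 25.9-fold higher and the adipogenic regulator Pparg at least 21.5-fold higher. The fatty acid elongase Elovl3 was 13.9-fold and the lipid droplet protein Plin2 6.71-fold higher. Of 16 epidermal differentiation genes, 7 were at least 2-fold higher on the early bulge array and 9 were less than 2-fold apart, 4 of them with the higher signal on the ORS array, with a median of 0.75 (99.97th percentile). Besides Klk7, these included Krtdap (11.1-fold), Sbsn (7.54-fold) and the calcium-binding protein Calm4 (4.57-fold). Among 15 basal keratinocyte and hemidesmosome genes, 6 were at least 2-fold higher on the early bulge array and 9 were less than 2-fold apart (median 0.69, 100th percentile). The hemidesmosome collagen Col17a1 was 5.20-fold higher, the laminin chains Lamb3 and Lama3 3.96-fold and 2.58-fold, and the cytolinker Dst 2.52-fold, with another probe set of Dst at a log2 ratio of 0.68. The median of this list was 0.40 when shared or ambiguous probe sets were left out.

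Some regulators of the hair matrix, the dividing compartment that forms the hair shaft, were higher on the ORS array. Of 17 measured, 7 were at least 2-fold higher on the ORS array, 10 were less than 2-fold apart, 5 of these with the higher signal on the early bulge array, and none was 2-fold higher there (median -0.66, 0th percentile). The homeobox genes Dlx3 (11.5-fold), Msx2 (10.3-fold), Dlx2 (9.52-fold) and Cux1 (7.01-fold) had the largest ratios. Other probe sets gave log2 ratios as weak as -0.80 for Dlx3, -1.12 for Msx2 and -0.23 for Cux1. Structural genes of the hair shaft and inner root sheath went both ways. Of 23 measured, 6 were at least 2-fold higher on the early bulge array and 4 on the ORS array, with a median of 0.36 (98.6th percentile, 96.6th among the 19 genes left by a floor at the 60th percentile). The inner root sheath keratins Krt28 (log2 ratio -3.58) and Krt71 (3.12-fold) were higher on the ORS array. The hair shaft keratins Krt33b (at least 3.47-fold) and Krt33a (2.89-fold) were higher on the early bulge array. Near-identical keratins can share probes, so ratios of single keratins of this group are uncertain. Of 4 measured companion layer keratins, Krt6a and Krt17 (log2 ratio 1.59) were higher on the early bulge array, Krt75 was 5.70-fold higher on the ORS array, and Krt16 had a log2 ratio of 0.01. Their median of 0.80 (99.5th percentile) became 0.01 (46.4th) over 5 genes with a floor at the 20th percentile.

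Most cell cycle genes had lower signals on the early bulge array, mostly by less than 2-fold. Of 24 DNA replication genes, 23 were lower, 2 of them by at least 2-fold, with a median log2 ratio of -0.76 (0th percentile). All 24 mitotic genes were lower, 4 by at least 2-fold, with a median of -0.80 (0th percentile). The replication licensing factor Cdc6 was 2.51-fold lower and Mcm10 2.21-fold lower, while the cyclins Ccne2 and Ccne1 had log2 ratios of -0.99 and -0.94. The spindle protein Tpx2 was 2.58-fold lower, the checkpoint kinase Bub1 2.34-fold, the kinase Aurkb 2.15-fold and the ubiquitin-conjugating enzyme Ube2c 2.11-fold. Another probe set of Tpx2 gave a log2 ratio of 0.27, and another of Mcm10 one of -0.03. The proliferation marker Mki67, named after its value was seen, was bright on both arrays (10648 and 12884, log2 ratio -0.27). Among 12 cell cycle inhibitors there was no common shift (median 0.14, 83.8th percentile). Cdkn1a, which encodes p21, was 3.70-fold higher on the early bulge array and Cdkn1c 2.16-fold higher on the ORS array. Gadd45a and Gadd45b had log2 ratios of -0.85 and 0.78.

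Genes of the Wnt, BMP, TGF-beta and Hedgehog pathways included members higher on either array. Among secreted Wnt inhibitors, Sostdc1 was 15.6-fold higher on the early bulge array (14786 and 949.5), Sfrp1 2.46-fold and Dkk3 2.43-fold, whereas Sfrp2 was at least 5.61-fold higher on the ORS array. The 9 measured inhibitors had a median of 0.32 (91.0th percentile), which was -0.07 after loess scaling and 0.77 (99.9th) with a floor at the 60th percentile. Of 9 Wnt target genes, only Lef1 was 2-fold apart, 6.11-fold higher on the ORS array, and the median was -0.21 (16.2th percentile). Axin2, Ccnd1 and Nkd1 had log2 ratios of 0.74, -0.38 and -0.37. Of 21 Wnt ligands and Frizzled receptors, 4 were at least 2-fold higher on each array. Fzd3 was 3.63-fold higher in early bulge, and Fzd4 (6.07-fold), Wnt5a (4.35-fold) and Fzd5 (3.03-fold) were higher in ORS. Other probe sets gave log2 ratios of 0.28 for Fzd3, -0.41 for Wnt5a and -0.97 for Fzd5, and, among the genes above, 0.53 for Sfrp1 and -0.83 for Lef1. The median was 0.46 (99.8th percentile, 96.4th after loess scaling) and the mean 0.04. Of 27 BMP and TGF-beta pathway genes, 6 were at least 2-fold higher on the early bulge array and 7 on the ORS array. The ligands Tgfb3 (8.74-fold) and Tgfb2 (5.79-fold), the latent TGF-beta binding protein Ltbp1 (7.99-fold) and Fst were higher in early bulge. The median of this list was -0.26 (1.07th percentile) and its mean 0.12, of opposite sign. The percentile lay between 2.95 and 3.84 under 4 alternatives, inside the central 95% of random lists. Of 10 Hedgehog pathway genes, the co-receptors Gas1 (3.35-fold), Boc (2.77-fold) and Cdon (2.36-fold) were higher in early bulge and the target Gli1 was 2.15-fold higher in ORS, with a median of -0.49 (0.31th percentile) and a mean of 0.02, again of opposite sign. A further probe set of Gas1 gave a log2 ratio of -0.86. None of 15 Notch pathway genes was 2-fold apart (median 0.12, 73.7th percentile). Heyl, Hey1, Rbpj and Jag1 had log2 ratios of -0.93, 0.72, 0.56 and -0.55, and another probe set of Jag1 gave 0.11.

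**Figure D2:**
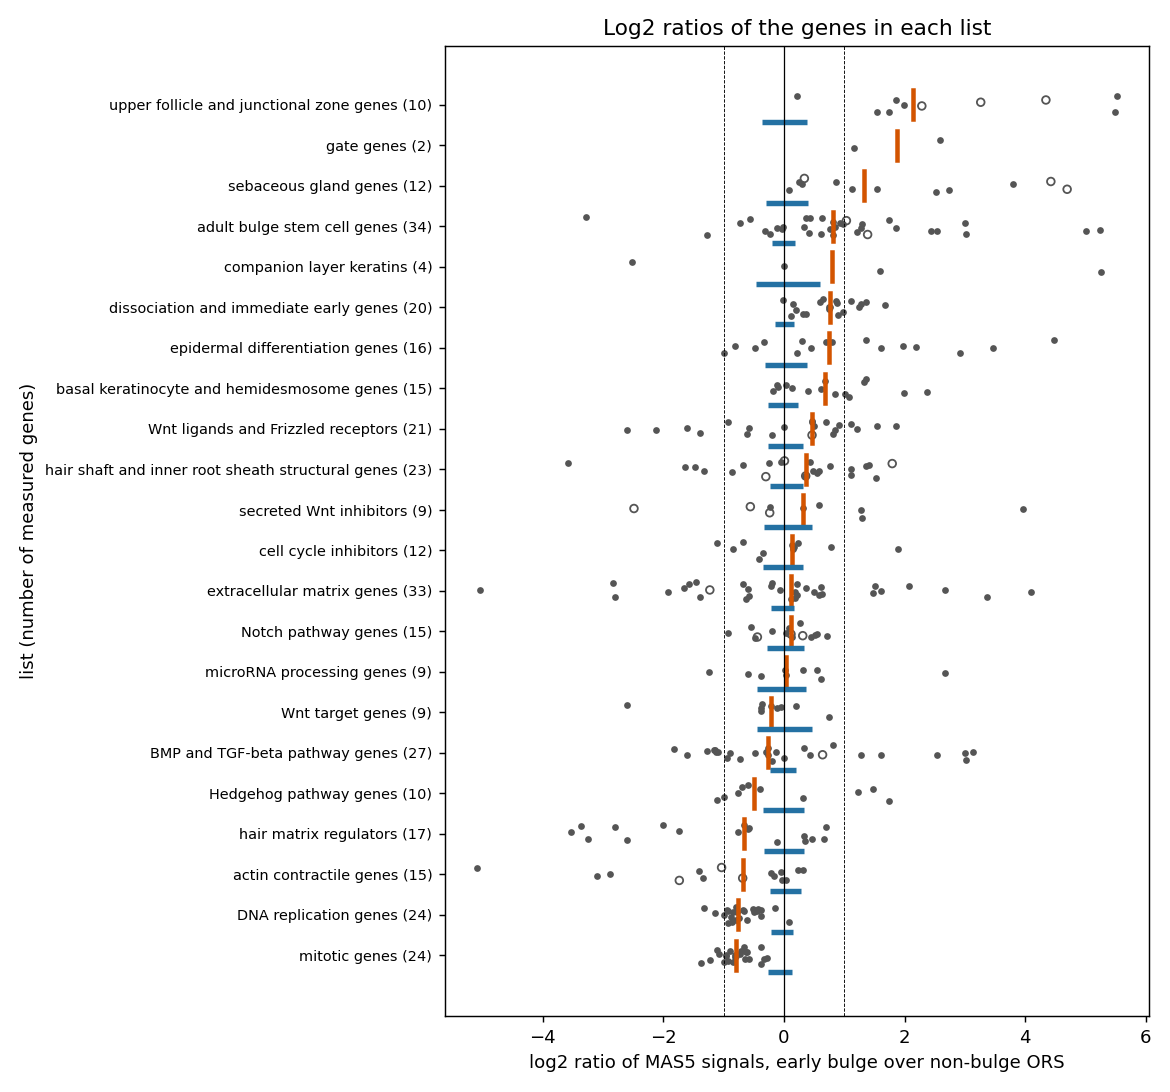
Log2 ratio of signals, early bulge over non-bulge ORS (horizontal axis), for each measured gene of each list (rows, number of genes in parentheses), with 1 array per population. Open circles are bounds with 1 array at the floor, orange bars are list medians, blue bars span the median of 10000 matched random lists plus and minus 2 SD, and dashed lines mark 2-fold. Among the lists shown with 3 or more genes, the upper follicle list has the highest median (2.14) and the mitotic list the lowest (-0.80).

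Extracellular matrix genes included members higher on either array. Of 33 measured, 7 were at least 2-fold higher on the early bulge array, 9 on the ORS array and 17 less than 2-fold apart (median 0.12, 92.8th percentile). Their mean of -0.07 had the opposite sign. Npnt and the basement membrane collagen Col4a4 (10.3-fold) were higher in early bulge. Thbs2 and the matrix glycoprotein Sparc (7.12-fold) were higher in ORS, although 1 probe set of Sparc gave a log2 ratio of 0.10. Of 15 actin contractile genes, 7 were at least 2-fold higher on the ORS array and none on the early bulge array (median -0.68, 0th percentile). Tagln, the smooth muscle actin Acta2 (8.58-fold, 11143 and 1299), Myl9 (7.38-fold) and Actg2 (at least 3.33-fold) were the largest. The median of this list was -0.16 (7.69th percentile) with the floor at the 60th percentile and -0.21 (8.27th) without shared or ambiguous probe sets.

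Markers of dermal fibroblasts, which should lie outside a keratin 14 gate, were higher on the ORS array, as were Thbs2, Sparc and the contractile genes named above. Of 13 measured, 12 were at least 2-fold higher on the ORS array, with a median log2 ratio of -3.35 (0th percentile). Lum, Dpt and Pdgfra were named above, and the collagen chain Col1a2 was 13.4-fold higher (14484 against 1079). Of 8 pericyte and smooth muscle markers, 4 were at least 2-fold higher on the ORS array (median -1.02, 0th percentile). Besides Tagln and Acta2 these were Pdgfrb (7.05-fold) and Rgs5 (2.56-fold), and 1 probe set of Rgs5 gave a log2 ratio of 0.74. Dermal papilla markers had a median of -0.02 (14.4th percentile), which was -0.77 (1.99th) after loess scaling. Of 11 measured, Wnt5a, Prom1 (3.47-fold) and Corin (at least 2.92-fold) were at least 2-fold higher in ORS, and Rspo3 had a bound of -0.89 on the log2 scale. The 11 melanocyte markers had no common shift (median 0.18, 64.2th percentile, mean -0.15). Kit (7.08-fold) and Ednrb (3.09-fold, with another probe set at a log2 ratio of 0.35) were higher in ORS, Slc45a2 was 2.41-fold higher in early bulge and Tyrp1 had a log2 ratio of 0.79. Another probe set of Kit gave -0.91.

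Markers of the remaining cell types were dim or few. The 6 measured immune markers had a median of 0.06 (34.4th percentile), and none of them was 2-fold apart. The 6 endothelial markers had a median of -0.40 (3.12th percentile), and Tek was 4.08-fold higher in ORS. The 4 Schwann cell markers had a median of 0.93 (98.5th percentile), with S100b 2.59-fold and Mbp 2.43-fold higher in early bulge, and other probe sets at log2 ratios of 0.78 for S100b and 0.05 for Mbp. That percentile was 96.9 and 97.1 with the floor at the 20th and the 60th percentile and 92.3 with the mean over probe sets. The 3 Merkel cell markers had a median of -0.56 (2.44th percentile), with Krt8 2.72-fold higher in ORS. That percentile was 2.63 after median centring, 4.65 after loess and 3.74 with a pseudocount. The 3 skeletal muscle markers had a median of -0.02 (27.2th percentile), and no erythroid marker was measured. Of 4 sex-linked transcripts none was 2-fold apart (median -0.29, 11.2th percentile). Xist had a log2 ratio of 0.46, and Kdm5d, Eif2s3y and Uty had ratios of -0.43, -0.35 and -0.22, all above the floor on both arrays. Another probe set of Uty had a ratio of 0.14.

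**Figure D3:**
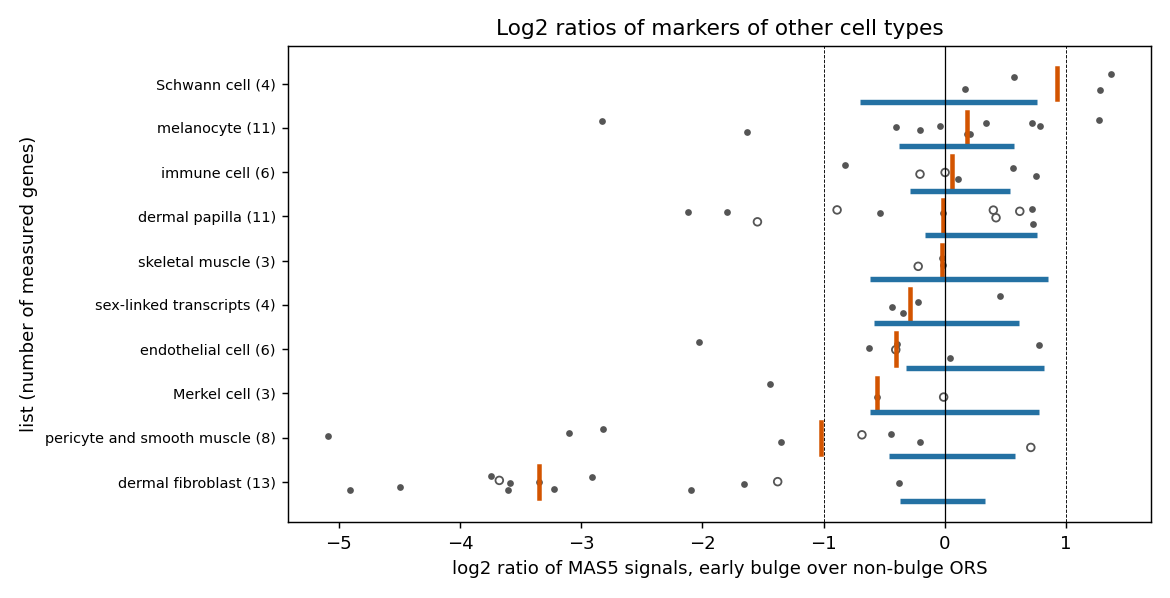
Log2 ratio of signals, early bulge over non-bulge ORS (horizontal axis), for each measured marker of other cell types and for sex-linked transcripts (rows, number of genes in parentheses), with 1 array per population. Symbols are as for the gene lists: open circles are bounds, orange bars medians, blue bars the matched random lists plus and minus 2 SD. The dermal fibroblast markers have a median of -3.35, and the other medians lie between -1.02 and 0.93.

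The list of immediate early and heat shock genes, fixed as genes that respond to tissue dissociation, was shifted towards the early bulge array. Of 20 measured, 19 were higher there and 5 by at least 2-fold (median 0.76, 100th percentile). Its heat shock genes Hsp90aa1, Hspa1a and Hspa1b, named after their values were seen, differed little, with log2 ratios of -0.011, 0.145 and 0.195. Their signals were among the brightest, between 15753 and 19150.5 on the 2 arrays. Only 531 probe sets on the early bulge array and 500 on the ORS array reached 10000. Whether signals this bright can show a difference was not tested. Dnajb1, named likewise, had one of 0.751. Socs3 (3.19-fold), Btg2 (2.57-fold), Zfp36 (2.42-fold) and Fosb (2.38-fold) had the largest ratios. This shift was present beside those of the stem cell, upper follicle and sebaceous lists. Control probe sets at the 3' and 5' ends of actin had log2 ratios of 0.28 and 0.11 at the deposited scale, and those of Gapdh -0.08 and -0.21. Within each array the 3' signals were well above the 5' signals. For actin they were 3.66 times as high on the early bulge array and 3.24 times on the ORS array. For Gapdh they were 3.79 and 3.47 times as high. Among 9 microRNA processing genes there was no common shift (median 0.03, 64.3th percentile), and the median was -0.01, -0.03 and -0.02 under the 3 other scalings. The Argonaute gene Ago4 was 6.34-fold higher in early bulge and Drosha, the nuclear microRNA processing enzyme, 2.37-fold higher in ORS, with another probe set of Drosha at a log2 ratio of -0.87. Xpo5 and Dicer1 had log2 ratios of -0.59 and 0.61.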

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

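Probe sets that no gene comparison used also differed between the arrays. Of 4632 measured probe sets with no gene in the annotation used, 77 were at least 4-fold apart, 49 higher on the early bulge array and 28 on the non-bulge ORS array. They were looked at because they lie outside the gene counts. No explanation for them was tested.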

How the results depend on the processing

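No paired analysis was possible because each population has 1 array, and no replicate could be left out. Values below are given as main value first. Counts moved with the treatment of low signals and with the unit counted. Genes at least 2-fold higher in early bulge numbered 968, against 1870 (20th percentile floor), 616 (60th), 2731 (no floor and no filter, below called no floor) and 2025 (probe sets counted); those higher in ORS numbered 634, against 984, 1601 (no floor) and 1199 (probe sets). At 4-fold, 248 became 373 (20th), 147 (60th) and 979 (no floor), and 175 became 100 (60th) and 588 (no floor). Under the 3 scalings, the pseudocount, the probe set mean and the suffix filter, counts stayed within 1.5 times. The median log2 ratio of all measured genes was 0.04 and ranged from -0.06 (loess) to 0.08 (no floor).

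Of 31 lists with 3 or more measured genes, 19 had a median outside the central 95% of random lists, and between 15 and 18 of them stayed there, on the same side, under each alternative; in 6 cases fewer than 3 genes of a list were left and no value was given, 2 of them for the Merkel and 1 for the Schwann list. Some lists inside the central 95% in the main setting moved out of it. Secreted Wnt inhibitors stayed inside under 6 of 9 alternatives, dermal papilla and endothelial markers under 7, and extracellular matrix genes under 8. No list called shifted and no named gene at least 2-fold apart changed sign. Of the named genes' alternative values, 172 moved by more than the spread between probe sets (0.338) and 1071 did not. List medians moved by more than the SD of random lists in 42 cases and not in 231. With loess they became 1.90 (upper follicle), 1.56 (sebaceous), -0.071 (Wnt inhibitors), 0.22 (Wnt ligands and Frizzled) and -0.77 (dermal papilla), and with quantile scaling 0.28 (Wnt ligands and Frizzled). With the 20th percentile floor they became 2.96 (upper follicle), 0.009 (companion), 1.75 (sebaceous), 0.064 (Wnt inhibitors), -0.87 (contractile) and 0.31 (immune). With the 60th they became 1.80 (upper follicle), 1.59 (companion), 0.23 (hair shaft), 1.04 (epidermal), 1.97 (sebaceous), 0.77 (Wnt inhibitors), -0.16 (contractile), -3.11 (fibroblast), -1.42 (dermal papilla) and -0.20 (melanocyte). Without a floor they became 3.04 (upper follicle), 0.009 (companion), 1.95 (sebaceous), 0.064 (Wnt inhibitors) and -0.87 (contractile). With a pseudocount they became 0.31 (Wnt ligands and Frizzled), -0.47 (contractile), -3.17 (fibroblast) and -0.76 (pericyte). With the probe set mean they became 1.83 (upper follicle), 0.58 (Wnt inhibitors), 0.018 (matrix), -0.26 (microRNA processing), 0.87 (immediate early), -3.06 (fibroblast) and -0.66 (pericyte). With the suffix filter they became 0.40 (basal), 1.21 (epidermal), -0.21 (contractile) and -0.56 (pericyte). Without matching, the Merkel percentile was 4.90 in place of 2.44. Each floor changes which genes are measured; the cause of the other shifts was not tested. Signals near the floor limit what dim genes can show.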

Other observations

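The family scan, the 5 further gene lists and their tests were chosen after the fixed lists had been seen, and the comparison of melanocyte with fibroblast markers, the share of non-cycling cells and the gene Pcx of the sebocyte list also after their own values or a control probe set had been seen. Single genes named in this part were picked after their values were seen.

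Gene families grouped by symbol showed further differences. Of 218 families with 8 or more measured members, 22 had a median below the central 95% of matched random lists and 24 above it. By chance, 10.9 in all would be met if the genes of a family behaved like randomly drawn genes. They need not do so, so these counts are no test of the families. Mitochondrial ribosomal, nucleolar and nucleoporin genes had lower signals on the early bulge array, while those of cytosolic ribosomal proteins did not (medians 0.05 for 23 Rpl and 0.15 for 28 Rps genes). The 73 genes of mitochondrial ribosomal proteins (Mrpl and Mrps) had a median log2 ratio of -0.39, 67 of them were lower and none was 2-fold apart (1 was under each of the 3 other scalings). The 8 Nop genes of nucleolar proteins had a median of -0.70 (0.07th percentile), and the 18 Nup genes of nucleoporins one of -0.55 (0.04th percentile). The 9 measured kallikrein proteases had a median of 1.35 (99.99th percentile; 0.45 over 11 genes after loess), with 6 at least 2-fold higher in early bulge, and the 9 annexins one of 0.95 (100th percentile). The medians of the mitochondrial ribosomal, Nop, Nup, kallikrein and annexin genes did not change sign under median centring, quantile or loess scaling.

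The values of 3 homeobox families are given because they were seen to be large, with no test, and some of their genes also stand in the hair matrix list. All 5 measured Dlx genes were at least 2-fold higher on the ORS array (median -3.21), as were both Msx genes. All 6 measured Irx genes had higher signals on the early bulge array (median 1.25), 3 of them by at least 2-fold, and these directions held under the same 3 scalings. The 8 measured Hoxb genes had a median of 0.01, with none 2-fold apart. Irx3 had signals of 3770 and 260.8, Irx5 of 4125 and 771.8 and Irx4 of 4473 and 1175.

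Fibroblast genes were higher on the ORS array, and a candidate explanation is RNA of dermal fibroblasts in that sort, although the low-speed spin and the keratin 14 gate would remove such cells. Of 18 other measured fibroblast genes, 7 were at least 2-fold higher on the ORS array and 6 had higher signals on the early bulge array; of the 13 fibroblast markers, none in another list, 11 were above the floor on the early bulge array too. The median of the 18 genes, -0.66, lay at the 0.01th percentile of matched random lists. It missed the -1 set in advance, so the test did not decide. Fn1 was 7.17-fold higher in ORS (6938 and 968) while Timp2 (0.10) and Mmp2 (0.23) were not. Epithelial genes from a list of 23 had a median of 0.55, which goes with a lower keratinocyte share in the ORS sort (31.6% fewer would be needed) but also with higher levels of these genes in early bulge cells. The 23 genes did not shift alike: 19 had the higher signal on the early bulge array and 4 on the ORS array. Their quartiles were 0.134 and 0.795. Markers of other cell types were not raised alike on the ORS array, as melanocyte and fibroblast medians lay 3.53 apart. Pericyte and smooth muscle markers were also higher there (median -1.02). The comparison of melanocyte with fibroblast markers was set after both medians had been seen. It is thus no independent test of a general loss of keratinocytes. Loess scaling left the fibroblast median at -3.29. Expression of fibroblast genes by ORS cells themselves remains open and untested.

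Upper follicle and sebaceous genes were higher on the early bulge array, and cells of these parts may have been included in the sort, although large differentiated cells were gated out. A separate list of 16 measured sebocyte genes had a median of 0.305 (99.35th percentile), between the limits of 0.3 and 1 set in advance. Without Pcx the median was 0.21 (95.62th percentile), below 0.3 by less than its bootstrap SD (0.163). That median is the ratio of Plin5 (signals 66.8 and 36.8), which lay below the floor on the ORS array. Both medians rest on this bound and are themselves lower bounds, so the explanation stays open. Of the 16 genes, 3 were at least 2-fold higher on the early bulge array and 2 on the ORS array. Cers4 (5.11-fold) and Elovl6 (3.91-fold, log2 0.48 to 2.34 over probe sets) were higher. Fads1 was 2.82-fold lower (another probe set at -0.07) and Fads3 2.25-fold lower. A list of 15 genes of the cornified layer had a median of 0.67 (99.56th percentile), between the same limits, which also did not decide. This median is the ratio of Slurp1 (signals 92.0 and 22.9), which lay below the floor on the ORS array, and so is a lower bound. Only 10 of the 15 genes were above the floor on that array. After loess the cornified layer median was 0.41 and the sebocyte median 0.44. Sprr1a (9.37-fold) and Klk5 (8.47-fold) were higher. Loess scaling left the upper follicle median at 1.90, which argues against intensity-dependent scaling as the cause. Expression of these genes in early bulge cells cannot be told apart from inclusion of neighbouring cells, because no value of a bulk array assigns a transcript to a cell.

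Cell cycle genes were lower on the early bulge array, and a difference in the share of cycling cells is a candidate explanation. A separate list of 26 measured cell cycle genes, 24 of them lower on the early bulge array, had a median of -0.70, which bears on how general the shift is and not on its cause. Loess scaling left the median of the DNA replication and mitotic genes at -0.73, which argues against intensity-dependent scaling as the cause. If the shift came only from added non-cycling cells, these would have to make up 42.0% of the early bulge sort. The rest of that sort would then have to cycle as the ORS sort does. This figure cannot tell slower cycling of bulge cells from such an admixture.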
